A study of Mus musculus with 16 samples.

How the data were processed

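RNA from 4 tendons of C57BL/6J mice (Achilles, forepaw flexor, patellar and supraspinatus) was sequenced, with 4 libraries per tendon, numbered as mice 1 to 4 in the labels. Per the labels' protocols, total RNA was purified with a micro column kit and DNase I, and Illumina libraries were made and sequenced at a core facility. Whether equal numbers in different tendons mark the same animal is not given in the sources used here. Each library was assigned to its tendon and number from its label.

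The deposited gene table holds whole-number read counts for 41204 genes in 16 columns, with no normalization, as the authors deposited it. Per the submitters' processing notes, HISAT2, FastQC and edgeR were used with genome build mm10. The read counter, its strand setting, the annotation release and the tool versions are not given in the sources used here. Counts of antisense and overlapping genes, and of genes with near-identical copies, are therefore uncertain. A second deposited table gives the authors' log2 fold changes, p-values, FDR values and mean log2 CPM for 13452 genes in all 6 comparisons. Their design and filter are not given in the sources used here. That table was used only to set its counts of genes and directions beside those computed here.

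Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by tendon, which left 23754, and scaled with TMM. A robust quasi-likelihood model with 1 mean per tendon was fitted to all 16 libraries, with no covariate or block. The 6 pairwise contrasts, the test over all 4 tendons and the mean of forelimb minus hindlimb tendons were tested 2-sided, with Benjamini-Hochberg adjustment within each and a threshold of 0.05. A gene was distinct to a tendon when it passed in the same direction in all 3 contrasts with that tendon, and differed between limbs when it passed in the mean contrast and in all 4 cross-limb contrasts in 1 direction. Standard errors are the absolute log2 fold change divided by the square root of its F statistic. Levels are TMM-scaled CPM, and principal components used log2 CPM with a prior count of 2. Positions were taken from GENCODE for GRCm38, the same assembly as mm10, and all 192 genes named were found there.

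Gene lists, 38 in all, covered tendon and matrix, cartilage and bone, limb position, signalling, stress and clock, cell cycle, metabolism and ribosome genes, and markers of 14 other cell types. Each list with at least 5 tested members was tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move one way on balance, not whether they differ from other genes. Counts adjusted over the list alone use Benjamini-Hochberg within its members. The percent of counts in each list of other cell types was compared with exact 2-sided permutation tests over all 70 assignments of 8 libraries, adjusted over 84 tests.

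Genes were named by a rule. For each comparison it takes the 6 higher and 6 lower genes with the largest log2 fold change among those past the threshold, with a mean CPM of at least 10 and no overlap between groups. Unnamed and predicted genes, pseudogenes, mitochondrial transcripts and other cell type markers were left out of that part. It also takes up to 4 members past the threshold per described list in order of adjusted p, the genes of a fixed panel of tendon, cartilage, limb, muscle, blood, fat and skin genes, up to 8 higher and 4 lower genes distinct to each tendon, and 6 higher and 6 lower genes between limbs. Groups, tests, lists, this rule and the first set of other settings below were fixed before the data were examined. Values of some genes the rule takes are not reported here.

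The first set of other settings was size factors by the median-ratio method, no filter, a mean CPM of at least 5, DESeq2 1.42.0, limma 3.58.1 with voom, the mouse number as a block, the mean log2 CPM of muscle markers as a covariate, the 8 libraries of a comparison alone, an absolute log2 fold change of at least 1, leaving out each library, and shares of counts without mitochondrially encoded and haemoglobin genes. Further settings were chosen after seeing the data, namely leaving the Patellar libraries out of the fit, leaving out 7 rRNA-like genes, and leaving them out with every library thinned to the smallest remaining total. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

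The fitting steps were tested on counts simulated for 23754 genes from the mean levels, dispersions and sizes of these libraries. With no effect the edgeR test called 0 genes in each of the 6 comparisons. In simulated Flexor minus Achilles and Patellar minus Achilles comparisons, 33% and 32% of genes changed 2-fold were recovered. Of genes changed 4-fold, 57% and 67% were recovered, with 2 false among 92 calls and 5 false among 104. Real Patellar libraries varied more than the others (mean Pearson r 0.926, against 0.981 to 0.986). These simulated rates may not hold under such unequal spread. No libraries of a tendon agreed within sampling noise, with chi-square per degree of freedom of at least 47.5 between any pair. In a library 3 counts correspond to 0.0278 to 0.0868 CPM, the level below which a gene cannot be told from 0. These floors cover counting error only. No column belonged to an unmapped sample.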

Results

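RNA was measured by sequencing in 4 tendons of C57BL/6J mice, a common inbred laboratory strain. The Achilles tendon joins the calf muscles to the heel, and the patellar tendon joins the kneecap to the shin. The flexor tendon of the forepaw bends the digits, and the supraspinatus tendon belongs to the rotator cuff of the shoulder. Each tendon was represented by 4 libraries, 16 in all. The Achilles and patellar tendons belong to the hindlimb, and the flexor and supraspinatus tendons to the forelimb. The design evaluated mRNA differences between every pair of tendons.

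Total counts per library ranged from 84414005 to 97180849 in Achilles and from 97242489 to 106573353 in Flexor. They ranged from 34559686 to 63235636 in Patellar and from 86898889 to 107805065 in Supraspinatus. Genes with rRNA-like sequence (Lars2, CT010467.1, Gm15564, Gm23935, Gm26917, mt-Rnr1 and mt-Rnr2, grouped after their values were seen) took 29.7% ± 12.1 (SD, n = 4) of the Patellar counts. The same genes took 4.18% ± 0.665 of the Achilles, 2.17% ± 0.275 of the Flexor and 3.27% ± 0.329 of the Supraspinatus counts. Between 23499 and 29270 genes were detected in Patellar libraries, and between 28834 and 31570 in the other libraries.

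**Figure D1:**
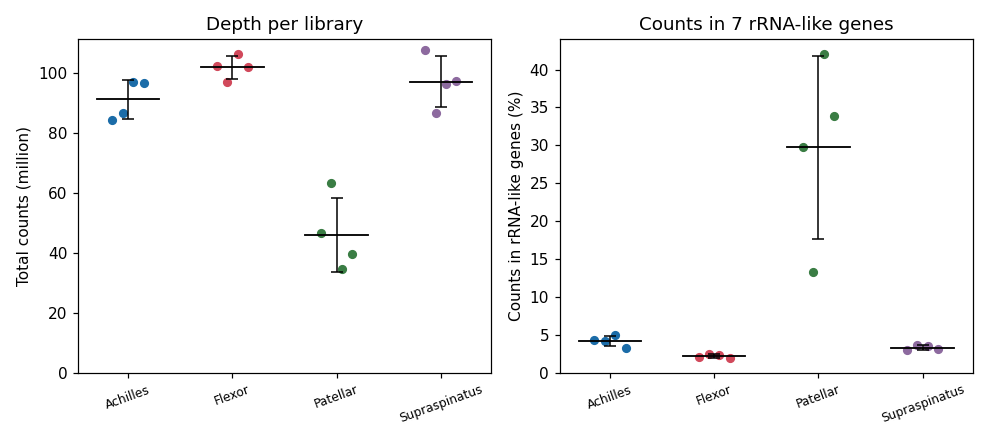
Total counts (left, the axis divided by 1e+06) and the percent of counts in 7 rRNA-like genes (right) for each of the 16 libraries, 1 point per library, with the mean as a line and 1 SD as bars. All 4 Patellar libraries, at 34.6 to 63.2 on that axis, lie below the other 12, and their rRNA-like share, at 13.2% to 42.0%, lies above.

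The tendons differed in 15420 of 23754 genes tested (edgeR quasi-likelihood test over all 4 tendons). In the fit of all 16 libraries, Flexor and Achilles differed in the fewest genes, 3853, and Supraspinatus and Patellar in the most, 12651. In fits of only the 8 libraries of a pair, the fewest were 5854, between Patellar and Achilles, and the most 10152, between Supraspinatus and Achilles. Libraries of one tendon correlated with a mean Pearson r of 0.981 in Achilles, 0.986 in Flexor, 0.926 in Patellar and 0.983 in Supraspinatus, across genes, which are not independent replicates. The first principal component of log2 CPM, with 40.4% of the variance, set the Patellar libraries apart from the others, and the second, with 18.6%, set the Supraspinatus libraries apart from the Achilles and Flexor libraries. Patellar replicate 3 stood apart from the other Patellar libraries on the third component, with 11.2%. In the authors' deposited table of 13452 genes, 3312 differed between Flexor and Achilles and 8449 between Supraspinatus and Patellar, and every gene called both there and here had the same direction.

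**Figure D2:**
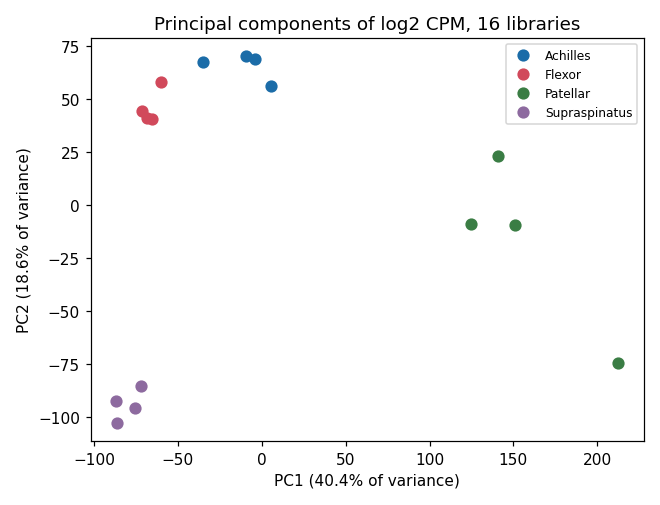
The first principal component (40.4% of variance, horizontal) and the second (18.6%, vertical) of log2 CPM, both in arbitrary units, with 1 point for each of the 16 libraries coloured by tendon. The Patellar points spread widest, with replicate 3 apart from the others.

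Of the 14 lists of markers of other cell types, skeletal muscle markers took the largest share of counts in all tendons but Patellar, where adipocyte markers took more. Muscle markers took 11.2% ± 3.49 in Achilles, 13.3% ± 1.97 in Flexor, 0.564% ± 0.641 in Patellar and 21.3% ± 0.754 in Supraspinatus (SD, n = 4). Adipocyte markers took 2.28% ± 0.784 in Achilles, 0.465% ± 0.104 in Flexor, 2.58% ± 1.26 in Patellar and 0.191% ± 0.0908 in Supraspinatus. Schwann cell and nerve markers took 0.385% ± 0.227, 0.397% ± 0.160, 0.0725% ± 0.0203 and 0.0465% ± 0.00340 in the same order, and osteoblast and bone markers 0.234% ± 0.0879, 0.109% ± 0.0396, 0.0145% ± 0.00643 and 0.00401% ± 0.00178. In exact two-sided permutation tests of 14 lists in 6 comparisons, 51 of 84 reached p = 0.0286, the smallest that 4 against 4 libraries can give, with an adjusted p of 0.0471. With mitochondrially encoded and haemoglobin genes left out of the total, 46 of 84 reached p = 0.0286 in the same exact permutation test and 0 passed the adjustment, the smallest adjusted p being 0.0522. With 1 library left out, 0 passed without any 1 of the Flexor or Supraspinatus libraries, Patellar replicate 3 or Patellar replicate 4 (smallest adjusted p from 0.0522 to 0.0667, exact permutation, 36 to 46 under 0.05 unadjusted), and 49 to 52 passed without any 1 of the others.

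**Figure D3:**
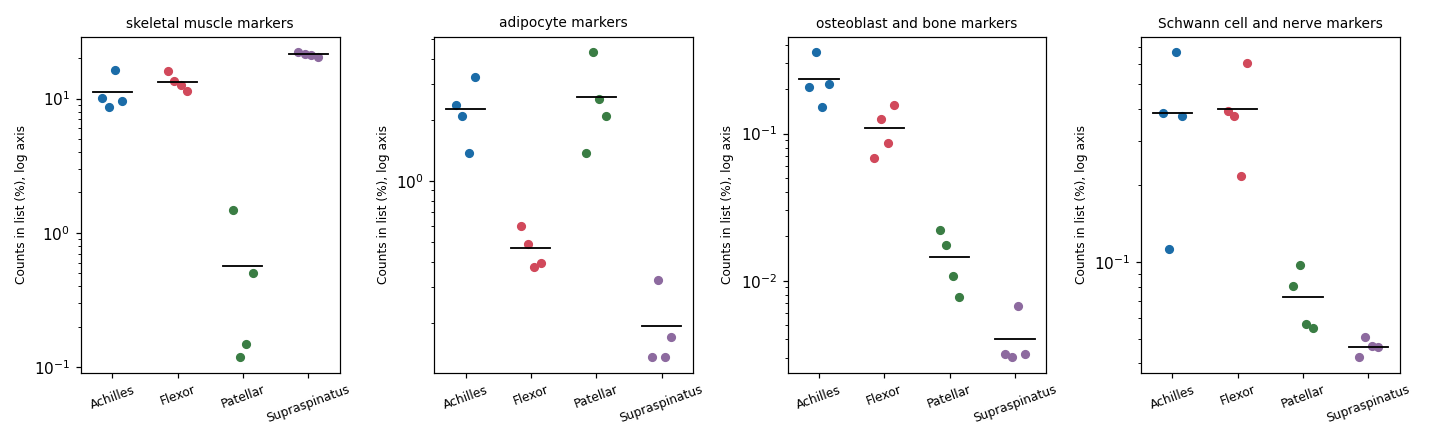
Percent of counts in 4 lists of cell type markers, on log axes, 1 point per library with the mean as a line. Skeletal muscle markers lie between 0.118% and 1.49% in the 4 Patellar libraries and between 20.4% and 22.3% in the 4 Supraspinatus libraries.

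Log2 fold changes are given as the first-named tendon minus the second with their standard errors, 4 libraries against 4, and levels as mean CPM ± SD of 4 libraries. Every gene given a fold change passed edgeR's test with Benjamini-Hochberg adjustment. Gene positions are whole gene spans on GRCm38 (mm10), with the identifiers of the deposited table. A gene list counts as past the test by camera with a preset correlation. An estimated correlation kept 4 of 14 lists in Flexor minus Achilles, 2 of 19 in Patellar minus Achilles, 2 of 18 in Supraspinatus minus Achilles, 4 of 18 in Patellar minus Flexor, 3 of 15 in Supraspinatus minus Flexor and 1 of 14 in Supraspinatus minus Patellar. Groupings that mixed both tendons of the 8 libraries of a pair also called lists, up to 23 in Flexor and Achilles libraries.

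Flexor and Achilles tendons differed in genes that pattern the limb and in fat genes, though the adipocyte list had adjusted p = 0.089 with an estimated correlation. Tbx5, a transcription factor of the forelimb (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219), was at 50.8 ± 5.31 CPM in Flexor and 0.315 ± 0.151 in Achilles. Pitx1, a transcription factor of the hindlimb (ENSMUSG00000021506, chromosome 13, 55825051 to 55836192), was at 0.226 ± 0.0863 CPM in Flexor and 19.3 ± 8.27 in Achilles. Coch, which codes for the secreted protein cochlin (ENSMUSG00000020953, chromosome 12, 51593341 to 51605771), was higher by 5.92 ± 0.56 (log2) and stood at 4591 ± 1281 CPM in Flexor. Ibsp, which codes for bone sialoprotein, was lower in Flexor.

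In all, 1543 genes were higher and 2310 lower in Flexor. Among the largest increases were Odf3l2 (6.49 ± 0.56 on the log2 scale), Mss51 (6.09 ± 0.55), the acetylcholine receptor subunit Chrne (5.93 ± 0.59) and the kinase gene Sbk3 (5.05 ± 0.68). The Wnt-binding factor Sfrp2 (-5.94 ± 0.95), Nnat (-5.62 ± 0.58), Meltf (-4.77 ± 0.72), haptoglobin Hp (-4.64 ± 0.65), Ppp1r27 (-4.31 ± 0.80) and Tmem45b (-4.29 ± 0.65) were among the largest decreases.

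Of the hindlimb identity genes, 5 of 7 were lower and 0 higher (5 and 1 adjusted over the list alone), camera adjusted p = 4.5e-22 (adjusted p = 0.0012 with an estimated correlation). Hoxc10 was at 0.0415 ± 0.0148 CPM in Flexor and 15.02 ± 2.66 in Achilles. Of the forelimb identity genes, 7 of 8 were lower and 1 higher (7 and 1 adjusted over the list alone), camera adjusted p = 1.4e-06 (adjusted p = 0.017 with an estimated correlation). Tbx5 was the member that was higher, while the homeobox genes Hoxc6 (0.0520 ± 0.0152 against 2.35 ± 0.322 CPM) and Hoxc5 (0.0640 ± 0.0326 against 1.91 ± 0.254 CPM) were lower in Flexor. Of the distal limb genes, 7 of 13 were higher and 0 lower (8 and 1 adjusted over the list alone), camera adjusted p = 2.1e-07 (adjusted p = 0.018 with an estimated correlation), and Hoxd13 was at 8.68 ± 1.25 CPM in Flexor and 0.104 ± 0.0937 in Achilles. Hoxd11 (3.34 ± 0.53) and Hoxd10 (2.004 ± 0.32) were also higher. Of the proximal limb genes, 5 of 11 were lower and 1 higher (5 and 1 adjusted over the list alone), camera adjusted p = 2.6e-05 (adjusted p = 0.026 with an estimated correlation), with Shox2 at -3.99 ± 0.20 and Meis2 at -2.83 ± 0.34.

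Of the adipocyte markers, 18 of 19 were lower and 0 higher (19 and 0 adjusted over the list alone), camera adjusted p = 5.3e-25 (adjusted p = 0.089 with an estimated correlation). They included the lipoprotein lipase gene Lpl (-3.24 ± 0.27), Thrsp (-2.63 ± 0.29), leptin Lep (-4.42 ± 0.49) and the fatty acid carrier Fabp4 (-3.53 ± 0.40). Of the fatty acid oxidation genes, 20 of 29 were lower and 1 higher (24 and 1 adjusted over the list alone), camera adjusted p = 2.1e-13 (adjusted p = 0.22 with an estimated correlation), with Acads (-1.14 ± 0.15) and Decr1 (-1.13 ± 0.15). Of the glycolysis genes, 12 of 28 were higher and 2 lower (15 and 2 adjusted over the list alone), camera adjusted p = 3.9e-06 (adjusted p = 0.2 with an estimated correlation). Pfkp (1.38 ± 0.20) and Pgk1 (0.98 ± 0.17) were higher, and Ldhb (-2.67 ± 0.49) was lower. Of the skeletal muscle markers, 14 of 86 were higher and 6 lower (15 and 6 adjusted over the list alone), camera adjusted p = 0.028 (adjusted p = 0.93 with an estimated correlation). Mstn, which codes for myostatin, was higher by 3.77 ± 0.35, and Myh7, the slow myosin heavy chain, was lower, at -8.26 ± 0.94. The muscle share of counts did not pass (exact permutation p = 0.371, adjusted p = 0.446).

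Of the osteoblast and bone markers, 4 of 14 were lower and 0 higher (4 and 0 adjusted over the list alone), camera adjusted p = 0.0056 (adjusted p = 0.2 with an estimated correlation), and Ibsp changed by -6.96 ± 0.53. Their share of counts did not pass (exact permutation p = 0.0571, adjusted p = 0.0873). Epidermis markers passed, with 5 of 15 higher and 1 lower (6 and 1 adjusted over the list alone), adjusted p = 0.0031 (adjusted p = 0.35 with an estimated correlation). They included Dmkn (4.45 ± 0.40) and Sbsn (2.25 ± 0.37). Endothelial markers passed, with 7 of 20 lower and 1 higher (10 and 1 adjusted over the list alone), adjusted p = 0.00028 (adjusted p = 0.69 with an estimated correlation). The share of counts did not pass (exact permutation p = 0.114, adjusted p = 0.17). The receptor gene Kdr was at -1.39 ± 0.26. Stress and immediate-early response genes passed, with 8 of 30 higher and 2 lower (8 and 2 adjusted over the list alone), adjusted p = 0.0035 (adjusted p = 0.44 with an estimated correlation). Atf3, a stress-induced transcription factor, was at 1.39 ± 0.20. Circadian clock genes passed, with 7 of 19 higher and 1 lower (8 and 1 adjusted over the list alone), adjusted p = 0.011 (adjusted p = 0.3 with an estimated correlation). Rora was at 1.09 ± 0.16. Cytoplasmic ribosomal protein genes passed, with 5 of 82 higher and 0 lower (0 and 0 adjusted over the list alone), adjusted p = 4e-08 (adjusted p = 0.75 with an estimated correlation).

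The count depended on which libraries entered the fit, at 6960 genes without the Patellar libraries, 6580 with these 8 libraries alone, and 2106 when an absolute log2 fold change of at least 1 was required. It was 2520 without Flexor replicate 2 and 2540 without Flexor replicate 3.

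Patellar and Achilles tendons differed in muscle and tendon genes, though with an estimated correlation skeletal muscle markers had adjusted p = 0.3 and tenogenic markers adjusted p = 0.69. Scx, a transcription factor of tendon cells (ENSMUSG00000034161, chromosome 15, 76457452 to 76459458), was at 102 ± 19.5 CPM in Patellar and 18.8 ± 5.32 in Achilles, 2.45 ± 0.29 on the log2 scale. Kera, which codes for the proteoglycan keratocan, was higher by 2.91 ± 0.58. The muscle sodium channel gene Scn4a was lower, at -5.93 ± 0.39.

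In all, 4130 genes were higher and 5001 lower in Patellar. Among the largest increases were Mab21l2 (5.34 ± 0.42), Faim2 (4.64 ± 0.47), Pon1 (4.13 ± 0.88), the water channel Aqp2 (4.07 ± 0.33), the metallothionein Mt3 (3.90 ± 0.54) and Hoxc8 (3.75 ± 0.25). Among the largest decreases were Scn4a, Myo18b (-5.63 ± 0.64), the amino acid transporter Slc38a3 (-5.36 ± 0.54), Myh14 (-5.36 ± 0.56), Trim72 (-5.26 ± 0.53) and Synpo2l (-5.20 ± 0.57).

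Of the skeletal muscle markers, 84 of 86 were lower and 0 higher (85 and 0 adjusted over the list alone), camera adjusted p = 7.9e-36 (adjusted p = 0.3 with an estimated correlation). Examples were Myom3 (-4.59 ± 0.38) and Xirp1 (-4.80 ± 0.45). Of the satellite cell markers, which label muscle stem cells, 7 of 9 were lower and 0 higher (7 and 0 adjusted over the list alone), camera adjusted p = 6.2e-07 (adjusted p = 0.026 with an estimated correlation), with Chodl at -3.84 ± 0.48. Of the oxidative phosphorylation genes, 88 of 107 were lower and 3 higher (92 and 4 adjusted over the list alone), camera adjusted p = 2.2e-20 (adjusted p = 0.52 with an estimated correlation), with Cyc1 at -1.99 ± 0.18 and Sdha at -1.83 ± 0.17. Of the glycolysis genes, 20 of 28 were lower and 1 higher (20 and 2 adjusted over the list alone), camera adjusted p = 1.9e-09 (adjusted p = 0.097 with an estimated correlation), with Slc16a1 at -1.99 ± 0.16 and Gapdh at -2.32 ± 0.22. Of the fatty acid oxidation genes, 23 of 29 were lower and 0 higher (23 and 0 adjusted over the list alone), camera adjusted p = 2e-11 (adjusted p = 0.3 with an estimated correlation), with Hadhb at -1.99 ± 0.20.

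Of the tenogenic markers, 8 of 21 were higher and 1 lower (9 and 1 adjusted over the list alone), camera adjusted p = 0.0064 (adjusted p = 0.69 with an estimated correlation). Cilp2 was higher (1.53 ± 0.32) and Egr2 lower (-1.96 ± 0.42). Tnmd, which codes for tenomodulin, was at 319.7 ± 79.2 CPM in Patellar and 182 ± 57.7 in Achilles and did not pass. Matrix remodelling and collagen processing passed, with 15 of 53 higher and 5 lower (15 and 5 adjusted over the list alone), adjusted p = 0.045 (adjusted p = 0.77 with an estimated correlation). Bmp1, a procollagen-processing protease, was higher (2.21 ± 0.26) and Adamts20 lower (-2.88 ± 0.33). Of the cytoplasmic ribosomal protein genes, 71 of 82 were higher and 1 lower (74 and 1 adjusted over the list alone), camera adjusted p = 1.6e-18 (adjusted p = 0.53 with an estimated correlation). Rpl39l and Rpsa, at 6.08 ± 0.34 and 1.46 ± 0.20, have related copies in the genome, and the rRNA-like share was 29.7% in Patellar and 4.18% in Achilles.

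Of the forelimb identity genes, 5 of 8 were higher and 0 lower (5 and 0 adjusted over the list alone), camera adjusted p = 6.6e-08 (adjusted p = 0.0056 with an estimated correlation), with Tbx5 at 4.63 ± 0.27 and Hoxc6 at 2.77 ± 0.19. Proximal limb genes passed, with 5 of 11 higher and 0 lower (6 and 0 adjusted over the list alone), adjusted p = 0.0016 (adjusted p = 0.091 with an estimated correlation). Emx2 was higher by 3.21 ± 0.32. Of the Schwann cell and nerve markers, 16 of 19 were lower and 0 higher (16 and 0 adjusted over the list alone), camera adjusted p = 4.4e-05 (adjusted p = 0.58 with an estimated correlation), with the myelin genes Mbp (-3.16 ± 0.53) and Prx (-4.00 ± 0.68) and with Drp2 (-3.51 ± 0.58). Red blood cell genes passed, with 6 of 8 higher and 0 lower (6 and 0 adjusted over the list alone), adjusted p = 0.0074 (adjusted p = 0.65 with an estimated correlation). Haemoglobin Hba-a1, which has a near-identical copy, was at 2.46 ± 0.41. Cytokines and chemokines passed, with 10 of 34 higher and 2 lower (14 and 2 adjusted over the list alone), adjusted p = 0.013 (adjusted p = 0.64 with an estimated correlation). They took 0.0894% ± 0.0216 of Patellar and 0.0982% ± 0.0249 of Achilles counts. Il33 was at 2.08 ± 0.29 and Cxcl13 at 5.17 ± 0.86.

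Pericyte and smooth muscle markers passed, with 11 of 16 lower and 0 higher (12 and 1 adjusted over the list alone), adjusted p = 0.00018 (adjusted p = 0.35 with an estimated correlation). Abcc9 was at -2.79 ± 0.24. Synovial lining and gliding surface markers passed, with 6 of 12 lower and 1 higher (6 and 1 adjusted over the list alone), adjusted p = 0.0036 (adjusted p = 0.28 with an estimated correlation). Osteoblast and bone markers passed, with 7 of 14 lower and 2 higher (7 and 2 adjusted over the list alone), adjusted p = 0.041 (adjusted p = 0.35 with an estimated correlation). Ibsp was at -4.33 ± 0.47. Endothelial markers passed, with 11 of 20 lower and 0 higher (13 and 0 adjusted over the list alone), adjusted p = 0.013 (adjusted p = 0.84 with an estimated correlation). The share of counts did not pass (exact permutation p = 0.114, adjusted p = 0.17). Adipocyte markers passed, with 3 of 19 higher and 1 lower (3 and 1 adjusted over the list alone), adjusted p = 0.038 (adjusted p = 0.89 with an estimated correlation). The share of counts did not pass (exact permutation p = 0.714, adjusted p = 0.81). Cell cycle genes passed, with 12 of 36 higher and 1 lower (9 and 1 adjusted over the list alone), adjusted p = 0.028 (adjusted p = 0.63 with an estimated correlation). The proliferation gene Mki67 was at 2.60 ± 0.42.

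With the mean log2 CPM of muscle markers as a covariate, 3403 genes differed, the calls ended for Kera, Cilp2, Egr2, Chodl, Gapdh, Hadhb, Mbp, Prx, Drp2, Hba-a1 and Pon1, and the sign of Cxcl13 turned (-0.20). The count was 5613 among genes with a mean CPM of at least 5, 5391 with an absolute log2 fold change of at least 1, and 5854 in the fit of these 8 libraries alone.

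Supraspinatus and Achilles tendons differed in bone, cartilage, fat and nerve-sheath genes, of which the bone list alone passed with an estimated correlation (cartilage adjusted p = 0.21, fat adjusted p = 0.21, nerve sheath adjusted p = 0.19). Ibsp (ENSMUSG00000029306, chromosome 5, 104299171 to 104311469) was at 0.472 ± 0.159 CPM in Supraspinatus and 514 ± 238 in Achilles, and Spp1, which codes for osteopontin, was lower, at -6.28 ± 0.69 (log2). Leptin Lep (-6.02 ± 0.54) was lower.

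In all, 4014 genes were higher and 3958 lower in Supraspinatus. Igfn1 was at 61.5 ± 31.3 CPM in Supraspinatus and 0.353 ± 0.299 in Achilles. Odf3l2 (6.98 ± 0.57), Mss51 (6.43 ± 0.56), Tbx5 (6.002 ± 0.28), the Wnt pathway ligand Rspo1 (5.50 ± 0.46) and Lrtm2 (5.30 ± 0.49) were also higher. Ugt8a, which makes a myelin lipid (0.110 ± 0.103 against 26.0 ± 20.5 CPM), the chitinase-like gene Chil1 (-7.70 ± 0.44), the ATP-gated channel P2rx1 (-7.50 ± 0.96), Nnat (-7.39 ± 0.63), Meltf (-7.23 ± 0.83) and the complement gene C7 (-6.26 ± 0.78) were lower.

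Of the osteoblast and bone markers, 8 of 14 were lower and 0 higher (8 and 0 adjusted over the list alone), camera adjusted p = 8.9e-06 (adjusted p = 0.045 with an estimated correlation). Of the cartilage and fibrocartilage markers, 9 of 23 were lower and 2 higher (9 and 2 adjusted over the list alone), camera adjusted p = 0.00028 (adjusted p = 0.21 with an estimated correlation), with Cytl1 at -5.00 ± 0.59 and Ucma at -5.27 ± 0.63, while Sox6 was higher (1.35 ± 0.18). Of the collagens, 15 of 43 were lower and 4 higher (16 and 5 adjusted over the list alone), camera adjusted p = 0.0056 (adjusted p = 0.65 with an estimated correlation), and the basement membrane chains Col4a4 (-1.97 ± 0.24) and Col4a3 (-1.96 ± 0.29) were lower. Of the Schwann cell and nerve markers, 18 of 19 were lower and 0 higher (19 and 0 adjusted over the list alone), camera adjusted p = 3.9e-15 (adjusted p = 0.19 with an estimated correlation), with Sox10 at -6.04 ± 0.61 and Mbp at -5.77 ± 0.60. Of the adipocyte markers, 18 of 19 were lower and 0 higher (18 and 0 adjusted over the list alone), camera adjusted p = 6.7e-16 (adjusted p = 0.21 with an estimated correlation), with Car3 at -3.72 ± 0.38 and Scd1 at -4.96 ± 0.52.

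Of the tenogenic markers, 7 of 21 were higher and 3 lower (7 and 3 adjusted over the list alone), not past camera (adjusted p = 0.64). They took 2.72% ± 1.04 of Supraspinatus and 3.997% ± 1.72 of Achilles counts. Scx (1.58 ± 0.28) and Kera (2.93 ± 0.58) were higher and Egr2 (-2.24 ± 0.42) lower. Kera was at 323 ± 354 CPM in Supraspinatus, with a difference of 1.81 without Supraspinatus replicate 4. Of the hindlimb identity genes, 6 of 7 were lower and 0 higher (7 and 0 adjusted over the list alone), camera adjusted p = 8.8e-11 (adjusted p = 0.0099 with an estimated correlation), and Hoxc10 was at 0.104 ± 0.138 CPM in Supraspinatus. Of the forelimb identity genes, 3 of 8 were higher and 1 lower (3 and 2 adjusted over the list alone), camera adjusted p = 0.0015 (adjusted p = 0.066 with an estimated correlation). Of the distal limb genes, 9 of 13 were lower and 2 higher (9 and 2 adjusted over the list alone), camera adjusted p = 0.0027 (adjusted p = 0.13 with an estimated correlation). Of the skeletal muscle markers, 30 of 86 were higher and 11 lower (35 and 11 adjusted over the list alone), camera adjusted p = 0.00017 (adjusted p = 0.9 with an estimated correlation), with Phkg1 (3.09 ± 0.23), Mstn (4.56 ± 0.36) and the myosin kinase Mylk4 (4.94 ± 0.46).

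Of the glycolysis genes, 14 of 28 were higher and 4 lower (15 and 5 adjusted over the list alone), camera adjusted p = 0.00019 (adjusted p = 0.31 with an estimated correlation), with Tpi1 at 1.67 ± 0.18 and Ldha at 1.57 ± 0.17. Mast cell markers passed, with 7 of 8 lower and 0 higher (7 and 0 adjusted over the list alone), adjusted p = 0.0046 (adjusted p = 0.48 with an estimated correlation). Endothelial markers passed, with 13 of 20 lower and 1 higher (14 and 1 adjusted over the list alone), adjusted p = 0.00032 (adjusted p = 0.69 with an estimated correlation). Pericyte and smooth muscle markers passed, with 9 of 16 lower and 2 higher (10 and 2 adjusted over the list alone), adjusted p = 0.0059 (adjusted p = 0.52 with an estimated correlation). The share of counts did not pass (exact permutation p = 0.2, adjusted p = 0.28). Fatty acid oxidation genes passed, with 11 of 29 lower and 0 higher (11 and 0 adjusted over the list alone), adjusted p = 0.0025 (adjusted p = 0.69 with an estimated correlation). Oxidative phosphorylation genes passed, with 18 of 107 higher and 3 lower (8 and 3 adjusted over the list alone), adjusted p = 0.0011 (adjusted p = 0.91 with an estimated correlation). They took 2.78% ± 0.301 of Supraspinatus and 2.91% ± 0.671 of Achilles counts. Stress and immediate-early response genes passed, with 11 of 30 higher and 2 lower (12 and 2 adjusted over the list alone), adjusted p = 0.0032 (adjusted p = 0.43 with an estimated correlation). The heat shock gene Hsph1 was at 2.10 ± 0.19. Circadian clock genes passed, with 9 of 19 higher and 0 lower (9 and 1 adjusted over the list alone), adjusted p = 0.013 (adjusted p = 0.32 with an estimated correlation). Nfil3 was at 2.35 ± 0.31. Mitochondrially encoded genes passed, with 7 of 13 higher and 0 lower (8 and 0 adjusted over the list alone), adjusted p = 0.013 (adjusted p = 0.81 with an estimated correlation). The cytochrome oxidase gene mt-Co3 was at 1.04 ± 0.26.

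The count of 7972 genes became 4775 when an absolute log2 fold change of at least 1 was required and 4720 among genes with a mean CPM of at least 5.

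Patellar and Flexor tendons differed in limb, fat, muscle and tendon genes, though with an estimated correlation adipocyte markers had adjusted p = 0.3, muscle markers adjusted p = 0.36 and tenogenic markers adjusted p = 0.69. Hoxc8 was at 33.4 ± 5.58 CPM in Patellar and 0.0230 ± 0.0113 in Flexor, and Pitx1 at 61.0 ± 15.7 and 0.226 ± 0.0863. Scx was higher in Patellar by 4.39 ± 0.32 (log2). Coch was at 8.81 ± 2.15 CPM in Patellar and 4591 ± 1281 in Flexor.

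In all, 5737 genes were higher and 6215 lower in Patellar. Hoxc9 (30.4 ± 9.80 against 0.0213 ± 0.0149 CPM), Hoxc10 (26.6 ± 6.27 against 0.0415 ± 0.0148 CPM), the keratin gene Krt17 (26.4 ± 12.9 against 0.0939 ± 0.157 CPM) and Sfrp2 (7.19 ± 0.997 on the log2 scale) were among the largest increases. Agbl1 (0.129 ± 0.0692 against 60.7 ± 13.04 CPM), Odf3l2 (0.115 ± 0.0496 against 36.6 ± 24.9 CPM), Chrne (0.108 ± 0.140 against 24.3 ± 7.45 CPM), the BMP antagonist Grem1 (0.153 ± 0.113 against 38.4 ± 50.6 CPM) and Mettl21e (0.140 ± 0.0649 against 30.8 ± 19.3 CPM) were among the largest decreases. Grem1 was at 114 CPM in Flexor replicate 4 and at 8.44 to 17.2 in the other Flexor libraries (log2 for Grem1, Patellar minus Flexor, -6.41 without that library).

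Of the adipocyte markers, 19 of 19 were higher and 0 lower (19 and 0 adjusted over the list alone), camera adjusted p = 5.2e-13 (adjusted p = 0.3 with an estimated correlation), with Thrsp (3.98 ± 0.31), Fabp4 (4.14 ± 0.41) and Lpl (2.47 ± 0.26). Of the tenogenic markers, 11 of 21 were higher and 1 lower (11 and 1 adjusted over the list alone), camera adjusted p = 0.0083 (adjusted p = 0.69 with an estimated correlation), with Cilp2 (3.16 ± 0.34), Kera (3.46 ± 0.60) and Ptx4 (2.50 ± 0.45). Matrix remodelling and collagen processing passed, with 22 of 53 higher and 6 lower (22 and 6 adjusted over the list alone), adjusted p = 0.018 (adjusted p = 0.71 with an estimated correlation). They included Bmp1 (2.74 ± 0.26), the protease inhibitor Timp2 (2.50 ± 0.26) and Mmp23 (2.71 ± 0.30). Of the cartilage and fibrocartilage markers, 13 of 23 were lower and 3 higher (13 and 3 adjusted over the list alone), camera adjusted p = 0.038 (adjusted p = 0.57 with an estimated correlation), with Cytl1 at -4.64 ± 0.58.

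Of the hindlimb identity genes, 5 of 7 were higher and 0 lower (5 and 0 adjusted over the list alone), camera adjusted p = 1.4e-07 (adjusted p = 0.021 with an estimated correlation). Of the forelimb identity genes, 6 of 8 were higher and 1 lower (7 and 1 adjusted over the list alone), camera adjusted p = 4.1e-08 (adjusted p = 0.0056 with an estimated correlation), with Hoxc6 (16.1 ± 2.18 against 0.0520 ± 0.0152 CPM) and Hoxc5 (10.8 ± 1.92 against 0.0640 ± 0.0326 CPM) higher in Patellar, the hindlimb tendon, and Tbx5 lower. Of the proximal limb genes, 8 of 11 were higher and 0 lower (8 and 0 adjusted over the list alone), camera adjusted p = 1.2e-06 (adjusted p = 0.015 with an estimated correlation), with Shox2 at 5.46 ± 0.22 and Emx2 at 3.33 ± 0.32. Of the distal limb genes, 11 of 13 were lower and 2 higher (11 and 2 adjusted over the list alone), camera adjusted p = 0.00028 (adjusted p = 0.093 with an estimated correlation), and Hoxd13 was at 0.0154 ± 0.0181 CPM in Patellar. Lhx9 was a member that was higher (5.25 ± 0.50).

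Of the skeletal muscle markers, 79 of 86 were lower and 2 higher (80 and 2 adjusted over the list alone), camera adjusted p = 2.9e-27 (adjusted p = 0.36 with an estimated correlation), with Mstn (-6.33 ± 0.41) and Phkg1 (-3.03 ± 0.23). Of the satellite cell markers, 7 of 9 were lower and 0 higher (7 and 0 adjusted over the list alone), camera adjusted p = 4.4e-05 (adjusted p = 0.051 with an estimated correlation). Of the glycolysis genes, 20 of 28 were lower and 0 higher (20 and 0 adjusted over the list alone), camera adjusted p = 7.9e-13 (adjusted p = 0.045 with an estimated correlation), with Gapdh (-3.35 ± 0.23) and Gpi1 (-2.56 ± 0.18). Of the oxidative phosphorylation genes, 93 of 107 were lower and 5 higher (94 and 6 adjusted over the list alone), camera adjusted p = 3.6e-13 (adjusted p = 0.65 with an estimated correlation), with Sdha at -1.82 ± 0.17, while Cox8a was higher (1.22 ± 0.12). Of the Schwann cell and nerve markers, 17 of 19 were lower and 0 higher (17 and 0 adjusted over the list alone), camera adjusted p = 3.9e-05 (adjusted p = 0.57 with an estimated correlation), with S100b (-3.02 ± 0.40) and Drp2 (-3.83 ± 0.59).

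Red blood cell genes passed, with 6 of 8 higher and 0 lower (6 and 0 adjusted over the list alone), adjusted p = 0.0063 (adjusted p = 0.64 with an estimated correlation). Cytoplasmic ribosomal protein genes passed, with 33 of 82 higher and 1 lower (31 and 1 adjusted over the list alone), adjusted p = 0.00032 (adjusted p = 0.9 with an estimated correlation), beside rRNA-like shares of 29.7% in Patellar and 2.17% in Flexor. Circadian clock genes passed, with 10 of 19 lower and 2 higher (11 and 2 adjusted over the list alone), adjusted p = 0.023 (adjusted p = 0.35 with an estimated correlation). Pericyte and smooth muscle markers passed, with 9 of 16 lower and 1 higher (10 and 1 adjusted over the list alone), adjusted p = 0.0024 (adjusted p = 0.47 with an estimated correlation). Synovial lining and gliding surface markers passed, with 7 of 12 lower and 1 higher (7 and 1 adjusted over the list alone), adjusted p = 0.0096 (adjusted p = 0.35 with an estimated correlation). The share of counts did not pass (exact permutation p = 0.0571, adjusted p = 0.087).

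With the muscle covariate 4719 genes differed, and the calls ended for Kera, Ptx4, Lpl, Cytl1, Drp2, Odf3l2 and Sfrp2. The count was 7688 with an absolute log2 fold change of at least 1 and 6904 among genes with a mean CPM of at least 5.

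Between the forelimb tendons, Supraspinatus had more RNA of proximal limb genes and Flexor more of distal limb genes. Cartilage and nerve-sheath genes differed too, with adjusted p = 0.092 and adjusted p = 0.097 with an estimated correlation. Scx was higher in Supraspinatus by 3.52 ± 0.31 (log2) and Shox2 by 3.17 ± 0.20. Hoxd13 was at 0.127 ± 0.116 CPM in Supraspinatus and 8.68 ± 1.25 in Flexor. Col9a1, which codes for a collagen of cartilage, was at 0.153 ± 0.0964 CPM and 18.0 ± 3.98. Coch was at 27.8 ± 17.9 CPM in Supraspinatus, against 4591 ± 1281 in Flexor.

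In all, 3492 genes were higher and 2949 lower in Supraspinatus. The channel gene Panx1 (4.34 ± 0.21), the netrin receptor Unc5a (3.99 ± 0.26), the potassium channel Kcna7 (3.65 ± 0.51), Carnmt1 (3.52 ± 0.32) and Kera (3.48 ± 0.60) were higher. Grem1 (0.171 ± 0.104 against 38.4 ± 50.6 CPM), Ugt8a (0.110 ± 0.103 against 25.3 ± 13.3 CPM), P2rx1 (-7.64 ± 0.96), the Wnt antagonist Frzb (-6.63 ± 0.56) and the potassium channel Kcna1 (-6.63 ± 0.55) were lower. The log2 fold change was -6.25 for Grem1, Supraspinatus minus Flexor, without Flexor replicate 4, and 2.35 for Kera, Supraspinatus minus Flexor, without Supraspinatus replicate 4.

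Of the distal limb genes, 11 of 13 were lower and 2 higher (11 and 2 adjusted over the list alone), camera adjusted p = 9.3e-11 (adjusted p = 0.0056 with an estimated correlation), with Hoxd10 at -4.27 ± 0.36. Of the proximal limb genes, 8 of 11 were higher and 0 lower (8 and 0 adjusted over the list alone), camera adjusted p = 1.8e-07 (adjusted p = 0.0099 with an estimated correlation), with Meis2 (3.91 ± 0.36) and Meis1 (1.996 ± 0.22). Of the forelimb identity genes, 5 of 8 were higher and 1 lower (6 and 1 adjusted over the list alone), camera adjusted p = 1.7e-09 (adjusted p = 0.0056 with an estimated correlation). Hoxc6 (4.99 ± 0.551 against 0.0520 ± 0.0152 CPM) and Hoxc5 (6.38 ± 1.88 against 0.0640 ± 0.0326 CPM) were higher, and Tbx5, present in both, was lower (-1.32 ± 0.22).

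Of the cartilage and fibrocartilage markers, 13 of 23 were lower and 1 higher (13 and 1 adjusted over the list alone), camera adjusted p = 7.2e-07 (adjusted p = 0.092 with an estimated correlation), with Chil1 (-5.25 ± 0.40) and Cytl1 (-5.69 ± 0.61). Of the Schwann cell and nerve markers, 18 of 19 were lower and 0 higher (19 and 0 adjusted over the list alone), camera adjusted p = 2.3e-19 (adjusted p = 0.097 with an estimated correlation), with S100b (-4.21 ± 0.42) and Cdh19 (-5.62 ± 0.57). Of the collagens, 15 of 43 were lower and 5 higher (16 and 5 adjusted over the list alone), camera adjusted p = 0.0017 (adjusted p = 0.58 with an estimated correlation), with Col4a4 at -2.17 ± 0.24. Epidermis markers passed, with 5 of 15 lower and 1 higher (7 and 1 adjusted over the list alone), adjusted p = 0.0067 (adjusted p = 0.44 with an estimated correlation). They included Dmkn (-6.02 ± 0.44) and Sbsn (-2.48 ± 0.37).

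Skeletal muscle markers passed, with 12 of 86 higher and 7 lower (12 and 7 adjusted over the list alone), adjusted p = 0.045 (adjusted p = 0.95 with an estimated correlation). Oxidative phosphorylation genes passed, with 26 of 107 higher and 2 lower (26 and 2 adjusted over the list alone), adjusted p = 0.00048 (adjusted p = 0.91 with an estimated correlation). Uqcc1, an assembly factor of the respiratory chain, was at 0.91 ± 0.16. Mitochondrially encoded genes passed, with 8 of 13 higher and 0 lower (11 and 0 adjusted over the list alone), adjusted p = 0.0083 (adjusted p = 0.78 with an estimated correlation). Fatty acid oxidation genes passed, with 9 of 29 higher and 0 lower (9 and 0 adjusted over the list alone), adjusted p = 0.029 (adjusted p = 0.84 with an estimated correlation). Cpt2, of mitochondrial fatty acid import, was at 0.97 ± 0.18. Cytoplasmic ribosomal protein genes passed, with 24 of 82 lower and 1 higher (27 and 1 adjusted over the list alone), adjusted p = 9e-05 (adjusted p = 0.89 with an estimated correlation). Rpl3 was at -1.04 ± 0.16. Mast cell markers passed, with 6 of 8 lower and 0 higher (6 and 0 adjusted over the list alone), adjusted p = 0.0024 (adjusted p = 0.44 with an estimated correlation). Pericyte and smooth muscle markers passed, with 8 of 16 lower and 2 higher (8 and 2 adjusted over the list alone), adjusted p = 0.0035 (adjusted p = 0.47 with an estimated correlation). The share of counts did not pass (exact permutation p = 0.0571, adjusted p = 0.087). Osteoblast and bone markers passed, with 7 of 14 lower and 0 higher (7 and 0 adjusted over the list alone), adjusted p = 0.0067 (adjusted p = 0.23 with an estimated correlation).

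The count of 6441 genes became 3709 when an absolute log2 fold change of at least 1 was required.

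Supraspinatus and Patellar tendons differed in muscle, hindlimb, fat and collagen genes, of which the hindlimb list alone passed with an estimated correlation (muscle adjusted p = 0.36, fat adjusted p = 0.3, collagens adjusted p = 0.69). The myosin kinase gene Mylk4 was higher in Supraspinatus by 8.32 ± 0.54 (log2) and Nos1, the neuronal nitric oxide synthase, was at 198 ± 56.0 CPM against 0.791 ± 0.591. Col1a1, the main chain of tendon collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), was at 5046 ± 3558 CPM in Supraspinatus and 16111 ± 4145 in Patellar, -1.68 ± 0.44, a call that ended with the muscle covariate. The tendon transcription factor Mkx (-1.55 ± 0.27) and Nnat (-7.57 ± 0.64) were lower.

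In all, 6274 genes were higher and 6377 lower in Supraspinatus. Lrtm2 (27.4 ± 13.5 against 0.0503 ± 0.0367 CPM), Odf3l2 (51.2 ± 21.8 against 0.115 ± 0.0496 CPM), Igfn1 (61.5 ± 31.3 against 0.154 ± 0.132 CPM), Scn4a (7.83 ± 0.42) and Ano5 (7.69 ± 0.55) were among the largest increases. Krt17 (0.0255 ± 0.0317 against 26.4 ± 12.9 CPM), Hoxc9 (0.110 ± 0.107 against 30.4 ± 9.80 CPM), Hoxc10 (0.104 ± 0.138 against 26.6 ± 6.27 CPM), Hoxc8 (0.148 ± 0.0724 against 33.4 ± 5.58 CPM) and the fatty acid receptor Ffar2 (-6.26 ± 0.61) were among the largest decreases.

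Of the skeletal muscle markers, 77 of 86 were higher and 6 lower (78 and 6 adjusted over the list alone), camera adjusted p = 6.9e-27 (adjusted p = 0.36 with an estimated correlation), with Phkg1 (4.22 ± 0.25) and Mstn (7.11 ± 0.43). Of the satellite cell markers, 6 of 9 were higher and 1 lower (8 and 1 adjusted over the list alone), camera adjusted p = 7.8e-05 (adjusted p = 0.051 with an estimated correlation), with Chodl at 5.78 ± 0.52. Of the oxidative phosphorylation genes, 96 of 107 were higher and 3 lower (97 and 4 adjusted over the list alone), camera adjusted p = 1e-20 (adjusted p = 0.52 with an estimated correlation), with Uqcc1 (2.37 ± 0.17) and Sdha (2.13 ± 0.17). Of the glycolysis genes, 20 of 28 were higher and 3 lower (20 and 3 adjusted over the list alone), camera adjusted p = 1.6e-11 (adjusted p = 0.06 with an estimated correlation), with Tpi1 (2.95 ± 0.18) and Gpi1 (2.83 ± 0.19). Of the fatty acid oxidation genes, 17 of 29 were higher and 2 lower (17 and 2 adjusted over the list alone), camera adjusted p = 0.0083 (adjusted p = 0.77 with an estimated correlation), with Acadvl at 1.74 ± 0.20.

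Of the collagens, 20 of 43 were lower and 5 higher (20 and 5 adjusted over the list alone), camera adjusted p = 0.019 (adjusted p = 0.69 with an estimated correlation). Col4a4 (-3.44 ± 0.25) and Col4a3 (-2.86 ± 0.30) were lower, and Col22a1 was higher (4.96 ± 0.64). Matrix remodelling and collagen processing passed, with 18 of 53 lower and 8 higher (18 and 8 adjusted over the list alone), adjusted p = 0.036 (adjusted p = 0.77 with an estimated correlation). The protease gene Adamts5 was lower (-2.32 ± 0.19), and Adamts20 was higher (3.85 ± 0.34). Of the hindlimb identity genes, 6 of 7 were lower and 0 higher (6 and 0 adjusted over the list alone), camera adjusted p = 2.5e-06 (adjusted p = 0.045 with an estimated correlation), with Pitx1 at -2.30 ± 0.28. Of the adipocyte markers, 19 of 19 were lower and 0 higher (19 and 0 adjusted over the list alone), camera adjusted p = 9.8e-13 (adjusted p = 0.3 with an estimated correlation), with Lep (-6.40 ± 0.55) and Thrsp (-3.09 ± 0.30). Of the cytoplasmic ribosomal protein genes, 69 of 82 were lower and 1 higher (70 and 1 adjusted over the list alone), camera adjusted p = 9.4e-11 (adjusted p = 0.69 with an estimated correlation), with Rpl3 (-1.41 ± 0.16) and Rps12 (-1.45 ± 0.18), beside rRNA-like shares of 3.27% in Supraspinatus and 29.7% in Patellar.

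Red blood cell genes passed, with 7 of 8 lower and 1 higher (7 and 1 adjusted over the list alone), adjusted p = 0.0072 (adjusted p = 0.65 with an estimated correlation). Schwann cell and nerve markers passed, with 12 of 19 lower and 0 higher (12 and 0 adjusted over the list alone), adjusted p = 0.0023 (adjusted p = 0.69 with an estimated correlation). Mast cell markers passed, with 6 of 8 lower and 0 higher (6 and 0 adjusted over the list alone), adjusted p = 0.034 (adjusted p = 0.64 with an estimated correlation). Circadian clock genes passed, with 12 of 19 higher and 1 lower (12 and 1 adjusted over the list alone), adjusted p = 0.01 (adjusted p = 0.3 with an estimated correlation). Nr1d2, a clock repressor, was at 1.76 ± 0.21.

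With the muscle covariate 4286 genes differed, and the calls ended for Col22a1, Odf3l2, Acadvl and Nr1d2. Among genes with a mean CPM of at least 5, 7095 differed.

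**Figure D4:**
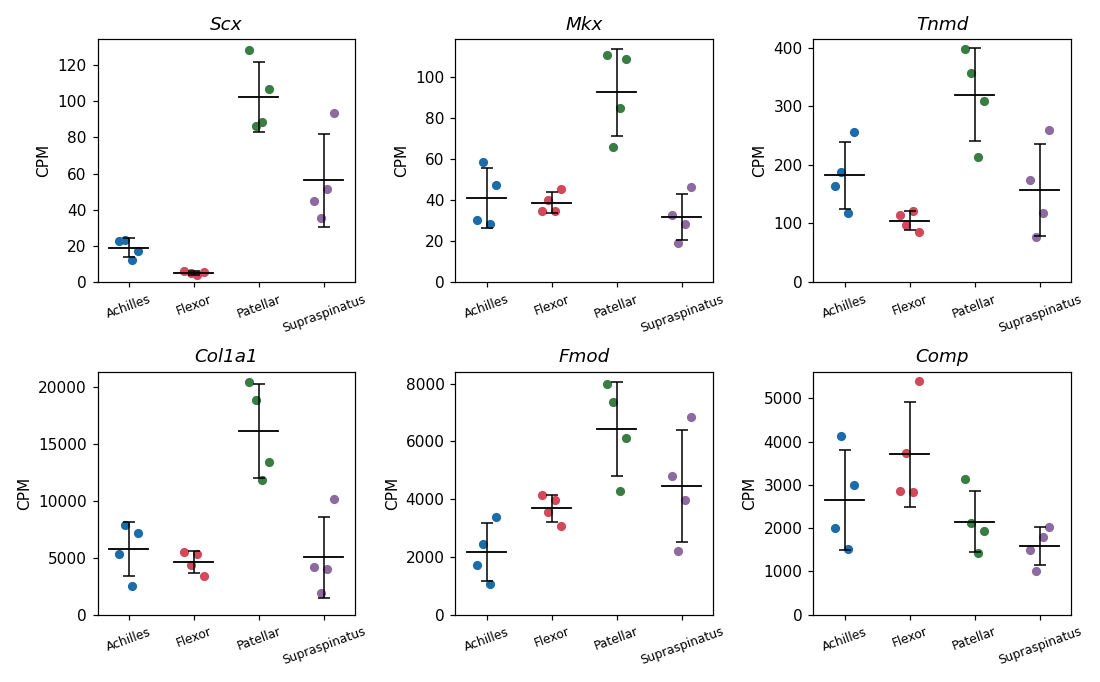
CPM of 6 tendon genes in each of the 16 libraries, 1 point per library, with the mean as a line and 1 SD as bars, on linear axes starting at 0. Scx lies lowest in Flexor, at 4.90 ± 1.10 CPM, and highest in Patellar, at 102 ± 19.5 CPM.

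Achilles had 274 genes higher and 138 lower than in all other tendons, Flexor 405 and 817, Patellar 2484 and 3363, and Supraspinatus 1677 and 1234. In Achilles, Tpm3, the tropomyosin of slow muscle fibres (ENSMUSG00000027940, chromosome 3, 90072649 to 90100902), was at 1763 ± 709 in Achilles, 117 ± 15.9 in Flexor, 201 ± 156 in Patellar and 63.3 ± 4.31 CPM in Supraspinatus, and its near-identical copy Tpm3-rs7 was higher as well. Meltf, at 31.9 ± 9.89 CPM, the transcription factor Isl1, at 10.1 ± 4.28, and the mitochondrial enzyme Idh2, at 913 ± 387, were also higher in Achilles. The alarmin Il33 was lower, at 22.2 ± 5.60 in Achilles, 82.1 ± 10.4 in Flexor, 94.0 ± 37.5 in Patellar and 225 ± 74.5 CPM in Supraspinatus.

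Flexor stood apart by Coch, by Sbk3 at 45.3 ± 11.7 CPM, by Col9a1 and by Hoxd11 at 17.1 ± 1.82 CPM, and by low Pitx1. Patellar stood apart by Hoxc8, by Mab21l2 at 38.4 ± 7.77 CPM, by Mt3 at 113 ± 66.6 and by Krt17 at 26.4 ± 12.9. Scn4a was lower in Patellar, at 1.11 ± 0.515 CPM. Lars2, one of the rRNA-like genes, and Rn7s2, whose sequence has close copies, were higher in Patellar too. Supraspinatus stood apart by Unc5a at 27.5 ± 3.88 CPM, the potassium channel Kcnc4 at 227 ± 53.9, the T-box factor Tbx1 at 43.2 ± 2.02, Shisa2 at 146 ± 13.4 and Igfn1. Kcna1, at 0.576 ± 0.115 CPM, and C7, at 0.948 ± 0.688, were lower in Supraspinatus.

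With the muscle covariate, 267 Achilles, 707 Flexor, 2032 Patellar and 1250 Supraspinatus genes were counted, and the calls against Patellar ended for Tpm3, Tpm3-rs7, Meltf, Isl1, Idh2, Sbk3 and Krt17, while the sign of C7 turned (0.28). With an absolute log2 fold change of at least 1 in each test the counts were 238, 478, 3333 and 1378.

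Forelimb tendons, Flexor and Supraspinatus, were set against hindlimb tendons, Achilles and Patellar. In all 4 cross-limb tests, 574 genes were higher and 734 lower in the forelimb. Nos1 was at 12.6 ± 5.97 in Achilles, 159 ± 9.01 in Flexor, 0.791 ± 0.591 in Patellar and 198 ± 56.0 CPM in Supraspinatus, and Odf3l2 at 0.405 ± 0.129 in Achilles, 36.6 ± 24.9 in Flexor, 0.115 ± 0.0496 in Patellar and 51.2 ± 21.8 CPM in Supraspinatus. Hoxc10 (ENSMUSG00000022484, chromosome 15, 102966796 to 102971893) was at 15.02 ± 2.66 CPM in Achilles and 26.6 ± 6.27 in Patellar, against 0.0415 ± 0.0148 in Flexor and 0.104 ± 0.138 in Supraspinatus. Nnat (ENSMUSG00000067786, chromosome 2, 157560078 to 157562522) was at 456 ± 177 in Achilles, 9.28 ± 5.04 in Flexor, 516 ± 215 in Patellar and 2.73 ± 2.09 CPM in Supraspinatus. Tbx5 was at 0.315 ± 0.151 in Achilles, 50.8 ± 5.31 in Flexor, 7.88 ± 0.961 in Patellar and 20.3 ± 2.45 CPM in Supraspinatus, and Pitx1 was at 12.4 ± 1.87 CPM in Supraspinatus.

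Mss51, Myhas, Sbk2 and Ache were also higher in the forelimb, and Ffar2, Klhdc7a, Ctcflos and Lgals12 in the hindlimb. Myhas and Ctcflos are antisense genes, and their reads cannot be told from those of their partners, since the strand setting is not given in the sources used here. Of 38 gene lists, 14 passed camera, 5 higher and 9 lower in the forelimb, and 3 of them also with an estimated correlation. Of the hindlimb identity genes, 6 of 7 were lower and 0 higher (6 and 0 adjusted over the list alone), camera adjusted p = 5.8e-15 (adjusted p = 0.0023 with an estimated correlation). Of the glycolysis genes, 21 of 28 were higher and 3 lower (21 and 3 adjusted over the list alone), camera adjusted p = 8.7e-14 (adjusted p = 0.035 with an estimated correlation). Of the satellite cell markers, 6 of 9 were higher and 1 lower (6 and 1 adjusted over the list alone), camera adjusted p = 0.00024 (adjusted p = 0.038 with an estimated correlation). Skeletal muscle markers passed, with 77 of 86 higher and 7 lower (77 and 7 adjusted over the list alone), adjusted p = 1.2e-25 (adjusted p = 0.36 with an estimated correlation). Adipocyte markers passed, with 19 of 19 lower and 0 higher (19 and 0 adjusted over the list alone), adjusted p = 3.3e-23 (adjusted p = 0.1 with an estimated correlation). Neutrophil and marrow markers passed, with 6 of 11 lower and 0 higher (6 and 0 adjusted over the list alone), adjusted p = 0.044 (adjusted p = 0.36 with an estimated correlation). Their share of counts was 0.000591% ± 0.000188 in Supraspinatus, 0.00342% ± 0.000759 in Flexor, 0.00305% ± 0.00111 in Achilles and 0.00320% ± 0.00205 in Patellar, and Flexor did not pass against either hindlimb tendon (exact permutation p = 0.6 and 0.914). Also past camera were matrix remodelling and collagen processing (19 of 53 lower, 6 higher), osteoblast and bone markers (8 of 14 lower, 2 higher), forelimb identity genes (6 of 8 lower, 1 higher), proximal limb genes (6 of 11 lower, 3 higher), red blood cell genes (7 of 8 lower, 1 higher), circadian clock genes (12 of 19 higher, 1 lower), oxidative phosphorylation genes (94 of 107 higher, 3 lower) and cytoplasmic ribosomal protein genes (24 of 82 lower, 3 higher), with the same counts adjusted over the list alone but for 23 lower ribosomal genes, and each with an adjusted p of at least 0.097 with an estimated correlation. The bone share was higher in Flexor than in Patellar (0.109% against 0.0145%, exact permutation p = 0.0286, adjusted p = 0.0471).

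The count of 1308 limb genes became 573 with the muscle covariate and 823 among genes with a mean CPM of at least 5. It was 758 with absolute log2 fold changes of at least 1 and 868 without Flexor replicate 2.

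**Figure D5:**
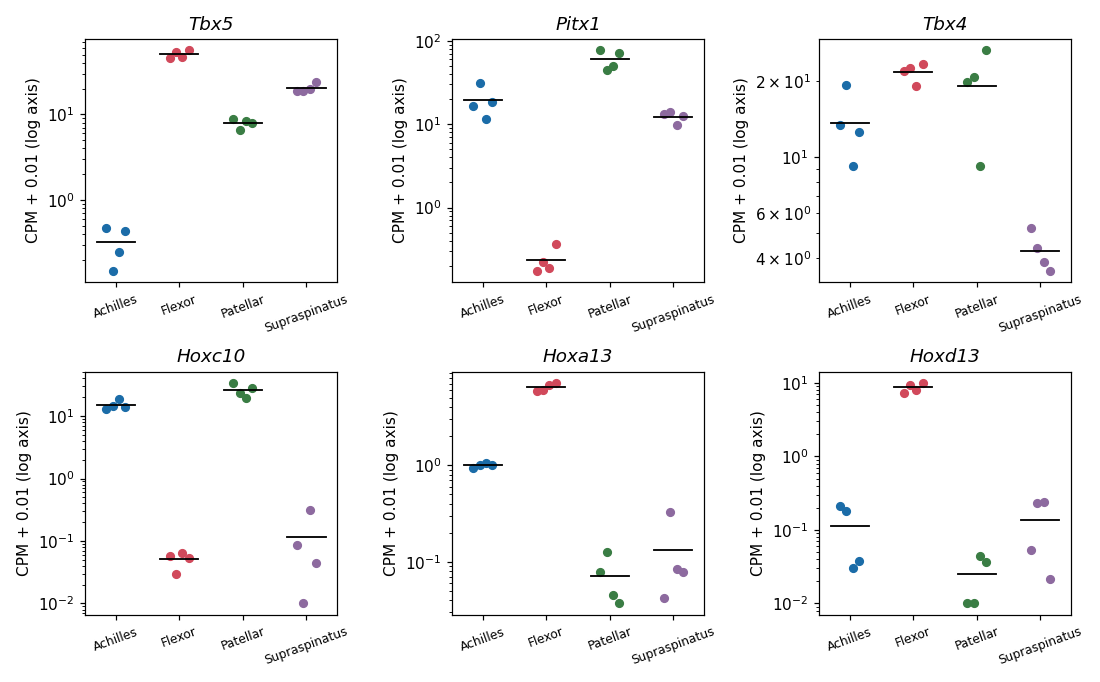
CPM plus 0.01 of 6 limb patterning genes on log axes, 1 point for each of 16 libraries with the mean as a line. Hoxd13 lies highest in Flexor, at 8.68 ± 1.25 CPM, and Hoxc10 in the 8 hindlimb libraries, at 15.02 ± 2.66 CPM in Achilles and 26.6 ± 6.27 in Patellar.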

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

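The tests of attached muscle, of depth and of muscle content as sources of the gene counts, and the split counts for genes were chosen only after the result was seen, as were the settings without rRNA-like genes used in both depth tests.

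In 12 of 167 sets of 4 libraries, 1 library stood apart, by Dixon's test of the gap to the nearest of the others against the range, and chance gives about 8.35. The share of osteoblast and bone markers in Supraspinatus replicate 3 was 0.00668%, against 0.00302% to 0.00317% elsewhere in the tendon. In Achilles replicate 3 the share of satellite cell markers was 0.450%, against 0.260% to 0.289% elsewhere in the tendon. The macrophage share in Supraspinatus replicate 2 was 0.240%, against 0.0821% to 0.108% elsewhere in the tendon. Epidermis markers had a share in Achilles replicate 4 that was 0.00537%, against 0.00757% to 0.00801% elsewhere in the tendon. Kera in Supraspinatus replicate 4 was 848 CPM, against 83.3 to 209 elsewhere in the tendon, as in each range that follows. Krt17 in Flexor replicate 1 was 0.329 CPM, against 0.00881 to 0.0200. Grem1 in Flexor replicate 4 was 114 CPM, against 8.44 to 17.2. Grem1 in Patellar replicate 1 was 0.322 CPM, against 0.0781 to 0.108. Tpm3 in Patellar replicate 1 was 435 CPM, against 115 to 129. Idh2 in Achilles replicate 3 was 1487 CPM, against 667 to 796. Il33 in Achilles replicate 3 was 13.9 CPM, against 24.0 to 26.0. Mt3 in Patellar replicate 4 was 212 CPM, against 71.3 to 92.0.

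Skeletal muscle markers were lowest in Patellar and highest in Supraspinatus. Lower depth and more rRNA-like counts in Patellar were argued against as the whole cause, since 75 of 86 muscle markers (87.2%) were still lower in Patellar than in each other tendon without rRNA-like genes and at equal depth. RNA from muscle attached to the samples may account for the pattern, and it stays open. Of 70 markers with a mean CPM of at least 100, 62 (88.6%) were lower in Patellar than in each other tendon, between the 50% below which this source would be excluded and the 90% set for it. A difference between the tendons themselves also stays open and was not tested.

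In the fit of all 16 libraries, the comparisons with Patellar called the most genes. That order did not hold in fits of the 8 libraries of each pair, where Supraspinatus minus Achilles called 10152, Supraspinatus minus Flexor 9536 and Patellar minus Achilles 5854, nor with the muscle covariate, where Supraspinatus minus Achilles called 7927 and Patellar minus Flexor 4719. Without rRNA-like genes and at equal depth, the smallest Patellar count was 7624 and the largest of a comparison without Patellar 6551, which argues against depth as the whole cause. Muscle content and the tendon cannot be told apart in these libraries. With the muscle covariate the median standard error of Patellar minus Achilles rose from 0.326 to 0.710, 2.17 times, while the median absolute log2 fold change went from 0.612 to 0.968, and what ended each call was not tested.

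No other grouping of the libraries gave such counts of genes. Groups that mix tendons have a wider spread, which lowers their counts, and library quality is not excluded as a source. In fits of the 8 libraries of a pair the real split was the only 1 of 35 with so many genes, at 6580 (Flexor and Achilles, highest other 1), 5854 (Patellar and Achilles), 10152 (Supraspinatus and Achilles), 9086 (Patellar and Flexor), 9536 (Supraspinatus and Flexor) and 9260 (Supraspinatus and Patellar), the highest other being 0 in the last 5. Of 100 splits of all 16 libraries, the real 1 alone reached 15420 genes differing between any tendons (highest other 22), 412, 1222, 5847 and 2911 genes distinct to Achilles, Flexor, Patellar and Supraspinatus, and 1308 between limbs (highest other 0 for each). Chance cannot be excluded for the number of gene lists past the test, though uneven mixes keep part of the tendon difference. In the same fits and order of pairs, 14, 2, 8, 6, 8 and 18 of 35 splits gave as many lists as the real 14, 19, 18, 17, 14 and 13, with highest others of 23, 20, 21, 20, 20 and 21.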

How the results depend on the processing

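The alternatives without the Patellar libraries or without rRNA-like genes were chosen after the data were seen. Among 498 pairs of a named gene and a comparison, 424 passed. Of these 498, the side of the threshold and the direction held for 497 with median-ratio size factors, 488 without a filter, 486 with limma voom, 479 of 486 with DESeq2, 494 of 495 without rRNA-like genes and 485 of 489 also at equal depth. Of 3984 values with 1 library left out, 43 calls ended, 23 were gained and 0 turned sign. With the muscle covariate 70 calls ended and 8 log2 fold changes turned sign, all of them then short of the threshold (adjusted p of at least 0.235, edgeR): Acta1 0.18, Ckm 0.75 and Cxcl13 -0.20 in Patellar minus Achilles, Acta1 0.37, Ckm 0.32 and Cish -1.89 in Patellar minus Flexor, C7 0.28 and Col2a1 1.51 in Supraspinatus minus Patellar. The cause of the ended calls and of the changed signs was not tested.

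With the muscle covariate the counts became 3403 (Patellar minus Achilles), 4719 (Patellar minus Flexor), 4286 (Supraspinatus minus Patellar), 267, 707, 2032 and 1250 (distinct to Achilles, Flexor, Patellar and Supraspinatus) and 573 (limbs). Among genes with a mean CPM of at least 5, where fewer genes were tested, they were 5613 (Patellar minus Achilles), 4720 (Supraspinatus minus Achilles), 6904 (Patellar minus Flexor), 7095 (Supraspinatus minus Patellar), 8914 (any tendons), 268 and 3651 (distinct to Achilles and Patellar) and 823 (limbs). With an absolute log2 fold change of at least 1, which can only remove genes, they were 2106 (Flexor minus Achilles), 5391 (Patellar minus Achilles), 4775 (Supraspinatus minus Achilles), 7688 (Patellar minus Flexor), 3709 (Supraspinatus minus Flexor), 238, 478, 3333 and 1378 (distinct, in the same order) and 758 (limbs). Flexor minus Achilles had 6960 genes with no Patellar libraries in the fit and 6580 with its own 8 libraries alone, and Patellar minus Achilles 5854 with its own 8 alone, and the cause was not tested. With 1 library left out, Flexor minus Achilles ranged from 2520 to 3465, and limbs from 868 to 1768 (without Patellar replicate 3). Lists past camera with an estimated correlation were those given above, with 3 of 14 for limbs, and fry called 25 for Supraspinatus minus Patellar. As given above, the share tests that passed ranged from 0 to 52. All other counts of genes, and of lists in the 6 comparisons, under these settings were within 1.5 times those in the text. Below 0.0278 to 0.0868 CPM, depth cannot show a gene.

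Equal mouse numbers did not deviate together, with a mean correlation of 0.0186 (-0.135 to 0.255, 2 of 24 pairs over 0.1, across genes), and 6 of 16 libraries correlated best with their own number. With the number as a block, the counts were 3555, 8510, 7518, 11436, 6145 and 12023 (comparisons in the order of the Results), 14673 (any), 396, 1130, 5443 and 2750 (distinct) and 1198 (limbs), and lists 13, 19, 18, 18, 15 and 15. Of the 498 pairs of gene and comparison, 4 calls ended and 5 were gained.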

Other observations

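The tests of muscle fibre genes were chosen only after the result was seen.

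Signalling genes moved in both directions between Supraspinatus and Achilles. Of the TGF-beta and BMP family signalling genes, 20 of 54 were higher and 12 lower (21 and 12 adjusted over the list alone), camera adjusted p = 0.083 (adjusted p = 0.57 with an estimated correlation). They included the receptor Bmpr1a (log2 fold change 1.45 ± 0.13, SE, as for the genes that follow) and the inhibitory factor Smad7 (1.34 ± 0.17). In FGF, IGF and PDGF signalling, 11 of 42 were higher and 12 lower (12 and 15 adjusted over the list alone), camera adjusted p = 0.84 (adjusted p = 0.97 with an estimated correlation), with Igfbp4 at -3.31 ± 0.33 and Igf2r at 1.31 ± 0.14. In Wnt signalling, 13 of 50 were higher and 12 lower (16 and 12 adjusted over the list alone), camera adjusted p = 0.78 (adjusted p = 0.95 with an estimated correlation), with the receptor Fzd7 at 2.07 ± 0.18. Of the hedgehog signalling genes, 4 of 13 were higher and 5 lower (4 and 5 adjusted over the list alone), camera adjusted p = 0.82 (adjusted p = 0.95 with an estimated correlation). Of the mechanosensing, adhesion and YAP/TAZ target genes, 12 of 43 were higher and 15 lower (13 and 16 adjusted over the list alone), camera adjusted p = 0.85 (adjusted p = 0.97 with an estimated correlation), with the integrins Itgb8 at -2.98 ± 0.31 and Itgav at 1.53 ± 0.16.

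Elastic fibre and proteoglycan genes also moved in both directions, again as genes in general did (33.6% of those tested differed). Of the elastic fibre genes, 4 of 24 were higher and 4 lower (4 and 4 adjusted over the list alone), camera adjusted p = 0.95 (adjusted p = 0.98 with an estimated correlation), with Fbln2 at 1.33 ± 0.18 and Fbn1 at 1.90 ± 0.28. Of the proteoglycans and small leucine-rich repeat proteins, 10 of 46 were higher and 12 lower (10 and 14 adjusted over the list alone), camera adjusted p = 0.54 (adjusted p = 0.93 with an estimated correlation), with Gpc1 at 2.15 ± 0.21.

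Macrophage and lymphocyte markers were also split between directions. Of the macrophage markers, 1 of 22 were higher and 2 lower (1 and 2 adjusted over the list alone), camera adjusted p = 0.84 (adjusted p = 0.98 with an estimated correlation), and of the lymphocyte markers, 3 of 15 were higher and 3 lower (3 and 5 adjusted over the list alone), camera adjusted p = 0.57 (adjusted p = 0.93 with an estimated correlation). None of these signalling, matrix, macrophage and lymphocyte lists passed camera in any of the 6 comparisons. Lymphocyte markers took 0.0182% ± 0.00223 of Supraspinatus and 0.00333% ± 0.00118 of Achilles counts (SD, n = 4, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0471). No share test passed without mitochondrially encoded and haemoglobin genes in the total and the lists, or without any 1 Supraspinatus library. That adjustment depends on how many tests of all lists reached the smallest p.

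Sarcomere genes of slow muscle fibres were high in Achilles. Myh7 made up 40.9% ± 7.25 of the CPM of adult myosin heavy chain genes in Achilles, 14.7% ± 6.70 in Patellar, 0.0612% ± 0.0310 in Flexor and 0.0208% ± 0.00238 in Supraspinatus (SD, n = 4). A hypothesis is that the muscle adjoining each tendon, of a different fibre type at each, may be the source. In all 5 gene families every Achilles library had a larger slow share than any Flexor or Supraspinatus library. The same held against Patellar libraries in 3 (myosin heavy chain, troponin T and troponin I). In troponin C the Patellar share, 84.3% ± 14.4, overlapped the Achilles share, 92.9% ± 0.925, and for the calcium pump Atp2a2 it was larger, 37.4% ± 18.5 against 13.8% ± 2.12. With muscle markers at 0.564% of Patellar counts and RNA of other cells untested, neither family can decide. The hypothesis stays undecided.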
